A study of Mus musculus with 8 samples.

How the data were processed

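Epididymal ducts of mouse embryos at E18.5 were profiled in 8 libraries, 4 control and 4 labelled Ptk7 conditional knockout. Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a TruSeq RNA kit, and sequencing was done on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were handled with STAR and featureCounts on GRCm38. Versions, the strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here. The authors deposited raw counts per gene, with 1 column per library and no normalization, for 46517 genes, and the summed exon length of each gene, which was not used in any test. Because the strand setting is not given, reads of overlapping antisense genes cannot be told apart, and near-identical genes such as the globins are uncertain.

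Gene symbols were matched by Ensembl identifier for 46005 genes, leaving 512 without a symbol. Of the genes, 38860 had the same chromosome, start and end as in GENCODE M21, an annotation of GRCm38. There were 19945 genes at 0 in every library. Total counts per library ranged from 24807970 to 29590547. The biological coefficient of variation was 15.2%, so counting error is small beside the spread between libraries for all but low genes. Every pair among the 28 pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 13.7 to 81.7 over genes with a summed count of at least 200), so no library was taken as a duplicate.

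The counts were tested with edgeR 4.0.16 (R 4.3.3) with TMM factors. The filter filterByExpr kept 16469 genes. The test was the quasi-likelihood F test on group over all 8 libraries, with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F, which is approximate. CPM values are scaled by the TMM factors. Before the data were examined, 28 gene lists were fixed (12 on the subject of the study and 16 of cell type or state markers, 998 genes, of which 4 were not found and 5 were matched by an older symbol). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated for each list, and with fry. Fry's p for a shared direction was the alternative fixed beforehand, and its mixed p, for changes in either direction, was added to the text after its values were seen. The score of a list is the mean over its genes of log2 CPM, with a prior count of 2, centred on each gene's mean, and scores were compared by exact two-sided permutation, whose smallest possible p with 4 against 4 is 0.0286.

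Named genes followed a rule also fixed before the data were examined. It took Ptk7 and the 6 largest rises and 6 largest falls among called genes (none were called). Those rises and falls needed a mean CPM of at least 1, no overlap between the groups and a symbol that is not a predicted name. The rule also took the 3 members of each study list and the 1 member of each marker list with the smallest p. Last came the 2 members with the highest level in each called marker list. This gave 63 genes. Other genes that are named, among them Acta2, Cdh1, Des, Grhl2, Ldb3 and Msln, were chosen after their values were seen. The results of 1 list and of some genes are not reported here, and the counts of flagged results and of values that changed sign or direction leave them out.

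Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, no filter on low counts, a minimum CPM of 1 in at least 4 libraries, DESeq2 1.42.0, limma voom with sample quality weights, 1 surrogate variable (sva 3.50.0), a block on the number in the title, and leaving out each library in turn. Alternatives added after seeing the data were DESeq2 and voom without the library labelled Ptk7 cKO 5, edgeR without that library and control 3, and edgeR with robust moderation.

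The code was tested on simulated counts drawn from the real means and library sizes for 16469 genes, for the comparison of knockout label with control. Of 50 genes changed at each size, edgeR recovered 2 at 1.25-fold, 25 at 1.5-fold, 43 at 2-fold and 49 at 4-fold, and DESeq2 recovered 8, 31, 44 and 49. Among the unchanged genes edgeR called 8 and DESeq2 40, and with no gene changed they called 0 and 5. A simulated shift of -0.27 in the duct epithelium list was called by camera with the preset (adjusted p = 2.42e-22) and with the estimated correlation (adjusted p = 0.0126). The simulated genes were drawn independently, whereas the real list had an estimated correlation of 0.318. The simulation therefore cannot show whether such a shift would be called in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.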

Results

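Gene expression was measured by RNA sequencing of total RNA in epididymal ducts, which derive from the Wolffian duct, dissected from E18.5 mouse embryos. There were 4 control libraries (numbered 1, 3, 4 and 6) and 4 libraries labelled Ptk7 conditional knockout, or cKO (numbered 1, 2, 4 and 5). Controls carried 1 floxed and 1 wild-type Ptk7 allele, and knockouts carried the floxed allele with the disrupted Xst87 allele. Both carried the T-Cre and mT/mG transgenes. Ptk7 encodes a transmembrane protein with an inactive kinase domain that acts in planar cell polarity and WNT signalling. Total counts ranged from 24807970 to 29590547 per library, and 16469 genes were tested. The labels do not say whether libraries came from separate embryos or litters, so p-values measure the spread between these samples, which may be partly technical.

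Ptk7 (ENSMUSG00000023972; GRCm38 chromosome 17, 46564451 to 46629504, minus strand) was checked first in every sample. It stood at 189, 112.5, 313 and 169 CPM (library-size normalised read counts) in controls 1, 3, 4 and 6, a mean of 195.9 ± 84.7 (SD, n = 4). The libraries labelled Ptk7 cKO 1, 2 and 4 had 7.33, 7.59 and 12.5 CPM, a mean of 9.15 ± 2.92 (SD, n = 3), which is 4.67% of the control mean. The library labelled Ptk7 cKO 5 had 194 CPM, from 4751 counts, or 99.2% of the control mean. Its Ptk7 level therefore goes against its label, and every direction given for the knockout group includes this library unless it is said to be left out. With all 8 libraries the log2 fold change of Ptk7 was -1.82 (SE 0.95, edgeR adjusted p = 0.655), and without the library labelled Ptk7 cKO 5 it was -4.42 (SE 0.37, edgeR adjusted p = 0.00805).

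**Figure D1:**
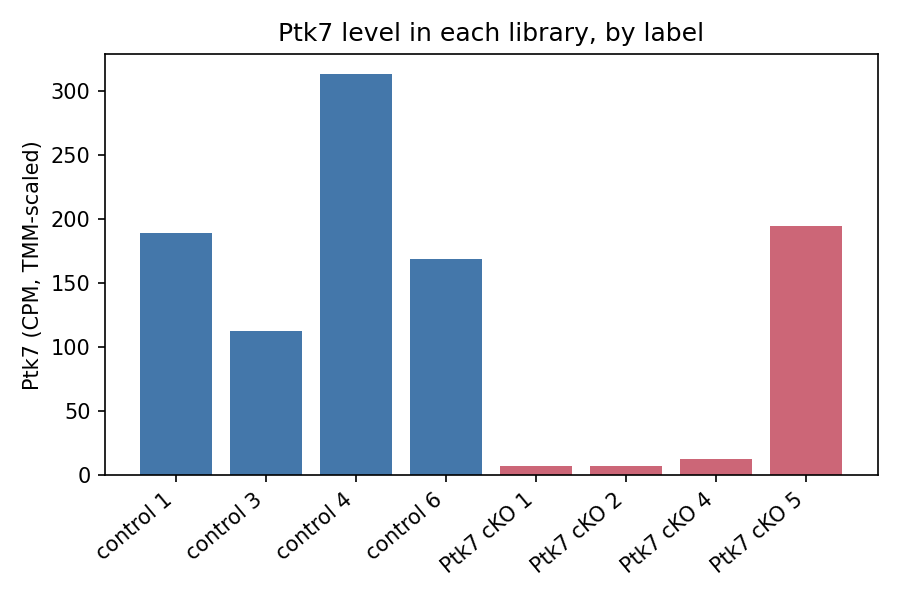
Ptk7 level in each of the 8 libraries, in CPM scaled by TMM factors (vertical axis), with 1 bar per library, blue for control and red for the knockout label. The libraries labelled Ptk7 cKO 1, 2 and 4 lie between 7.33 and 12.5 CPM, and the library labelled Ptk7 cKO 5, at 194 CPM, lies among the controls.

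The comparison of the knockout label with control was made to ask which genes differ in the duct when Ptk7 is removed. Because the library labelled Ptk7 cKO 5 kept Ptk7 at the control level, it compares labels and not Ptk7 levels. Markers of the duct epithelium were lower in the libraries labelled knockout, as were genes of smooth muscle differentiation, while markers of mesothelium (the lining of the body cavity) and of neurons and Schwann cells were higher. These 4 calls rest on a preset correlation between genes: each was lost when the correlation was estimated (adjusted p = 0.399 with an estimated correlation) and in the fry rotation test of a shared direction (0.228). Fry's mixed test, which asks whether members change in either direction, passed for each (adjusted p = 0.0361 for duct epithelium, 0.0094 for smooth muscle, 0.00929 for mesothelium and 0.0136 for neurons and Schwann cells). It does not test a shared direction, so it does not restore these calls. It also passed for lists that camera did not call, among them integrins, canonical WNT and testis. Among single genes, the polarity receptor Fzd6 was lower (63.2 ± 3.77 CPM in control, 42.4 ± 4.0 in knockout, SD, n = 4 each). The secreted ligand Wnt4 was higher (55.3 ± 7.97 against 77.8 ± 1.45), and the duct transcription factor Lhx1 was lower (39.0 ± 6.15 against 24.4 ± 3.26). In Fzd6, Wnt4 and Lhx1 the library labelled Ptk7 cKO 5 (43.8, 79.3 and 25.3 CPM) lay outside the control ranges (58.1 to 67.0, 45.5 to 64.3 and 31.5 to 44.3). These differences thus followed the label and not the Ptk7 level, though the genes were picked with that library included. In Amhr2 that library lay with the controls (2.29 CPM, controls 1.96 to 2.90). No gene passed an adjusted p of 0.05 over all genes in edgeR's quasi-likelihood test: 0 were called, and the smallest adjusted p was 0.161. At an unadjusted p under 0.05 there were 1379 genes, 577 higher and 802 lower, where chance gives 823. DESeq2 called 186 genes on the same libraries, 58 higher and 128 lower, and 188 without the library labelled Ptk7 cKO 5, of which 118 were in both sets with the same sign. These fits share all libraries but that one, so the overlap is not a replication. DESeq2 called 24 of the 63 named genes, against 186 of all 16469 tested. Most of the 63 were named for a small p in the same libraries, so that share is not separate support. In counts simulated with known changes, DESeq2 also called 40 unchanged genes and edgeR 8.

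Extracellular matrix genes were examined because the title of the series names matrix assembly. Npnt (nephronectin, a basement membrane ligand of integrins) was lower in the knockout label, with 160 ± 14.9 CPM in control and 118 ± 13.3 in knockout (log2 fold change -0.44, SE 0.10). It fell when adjusted over the list alone (edgeR adjusted p = 0.0288; 0.203 over all genes). It was the 1 member of the 30 basement membrane genes to do so, and the list as a set was not called (camera adjusted p = 0.345). Spon2 (log2 fold change 0.49, SE 0.12) and Tgfbi (0.45, SE 0.11), both secreted matrix proteins, each had an edgeR p adjusted over the list alone of 0.0561 and were called by DESeq2 (adjusted p = 0.0149 and 0.0196). The 23 interstitial collagens had a median log2 fold change of 0.12, with 17 above 0, and none passed when adjusted over the list alone. As a set the collagens were not called (camera adjusted p = 0.0732), nor were the 54 matrix glycoproteins and proteoglycans (0.0822) or the 60 matrix proteases, inhibitors and cross-linking enzymes (0.0598). The basement membrane list was called lower without the library labelled Ptk7 cKO 5 (camera adjusted p = 0.0266). With the correlation estimated over all 8 libraries the adjusted p was 0.895 for basement membrane and 0.807 each for collagens, glycoproteins and proteases. In fry's mixed test none of the 4 passed (adjusted p = 0.104 for basement membrane, 0.487 for collagens, 0.127 for glycoproteins and 0.174 for proteases). At the preset correlation the collagen list was called lower, the opposite direction, under the replicate block over 4 libraries (0.000836), and higher without control 1 (0.00195) or 4 (0.0454), or without the library labelled Ptk7 cKO 1 (0.0102) or 4 (0.0189). The glycoprotein list was called higher without control 1 (0.0219) or the library labelled Ptk7 cKO 1 (0.0268) or 4 (0.00482), and the protease list without control 1 (0.00282) or the library labelled Ptk7 cKO 1 (0.00268) or 2 (0.0365). Without the library labelled Ptk7 cKO 5 the camera adjusted p was 0.867 for collagens, 0.653 for glycoproteins and 0.688 for proteases, and for collagens it was 0.887 without control 3.

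With all 8 libraries no shared direction was called for myosin II or adhesion genes. Itgb6, the beta subunit of an epithelial integrin, was lower (2.33 ± 0.26 CPM in control, 1.19 ± 0.16 in knockout, log2 fold change -0.97, SE 0.19). It was the 1 member of the 45 integrin and focal adhesion genes to fall when adjusted over the list alone (edgeR adjusted p = 0.0197; 0.163 over all genes). Of 57 myosin II and actomyosin genes, Ppp1r14b, a relative of known myosin phosphatase inhibitors, rose (log2 fold change 0.60, SE 0.13, edgeR adjusted p = 0.0391 over the list alone). Ppp1r12b, a subunit of that phosphatase, fell (-0.48, SE 0.12, edgeR adjusted p = 0.0475 over the list alone). As sets, integrins (camera adjusted p = 0.308) and myosin II (0.599) were not called. Without the library labelled Ptk7 cKO 5 the integrin list was called lower at the preset correlation (0.0201), while over all 8 libraries with an estimated correlation its adjusted p was 0.823. In fry's mixed test integrins passed (adjusted p = 0.0304) and myosin II did not (0.218). Under the replicate block over 4 libraries myosin II was called lower (0.0481), the opposite direction from the 8 libraries.

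In the WNT and duct patterning lists, medians lay near 0 and members moved in both directions. At an unadjusted p under 0.05, 3 of 51 planar cell polarity and non-canonical WNT genes were higher and 9 lower. For 71 Wolffian duct regulators the counts were 6 and 15, and for 42 canonical WNT targets and antagonists 6 and 3. Over all 16469 genes they were 577 and 802. Of 51 planar cell polarity and non-canonical WNT genes, Fzd6 fell (log2 fold change -0.58, SE 0.08, edgeR adjusted p = 0.00166 over the list alone) and Wnt4 rose (0.49, SE 0.10, edgeR adjusted p = 0.00901 over the list alone). For both genes the ranges of the groups did not overlap, and DESeq2 called both over all genes (adjusted p = 1.27e-05 and 0.00209). Both were named for a small p in these libraries, so the lack of overlap adds no separate support. Over all genes 5.76% did not overlap, where chance gives 2.86%. Of 71 Wolffian duct regulators, Ros1 (-0.67, SE 0.12), Lhx1 (-0.67, SE 0.13) and Met (-0.50, SE 0.12) fell, with edgeR p adjusted over the list alone of 0.0116, 0.0127 and 0.0402. Ros1 is a receptor tyrosine kinase of the epididymal epithelium and Met is the receptor of hepatocyte growth factor. Duct epithelium markers were lower in the same libraries, with a median log2 fold change of -0.27. Neither list was called as a set (camera adjusted p = 0.356 and 0.450), nor were the 42 canonical WNT targets and antagonists (0.954). None of the latter passed over the list alone. In fry's mixed test all 3 lists passed (adjusted p = 0.0136 for planar cell polarity, 0.00929 for Wolffian duct regulators and 0.0488 for canonical WNT).

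**Figure D2:**
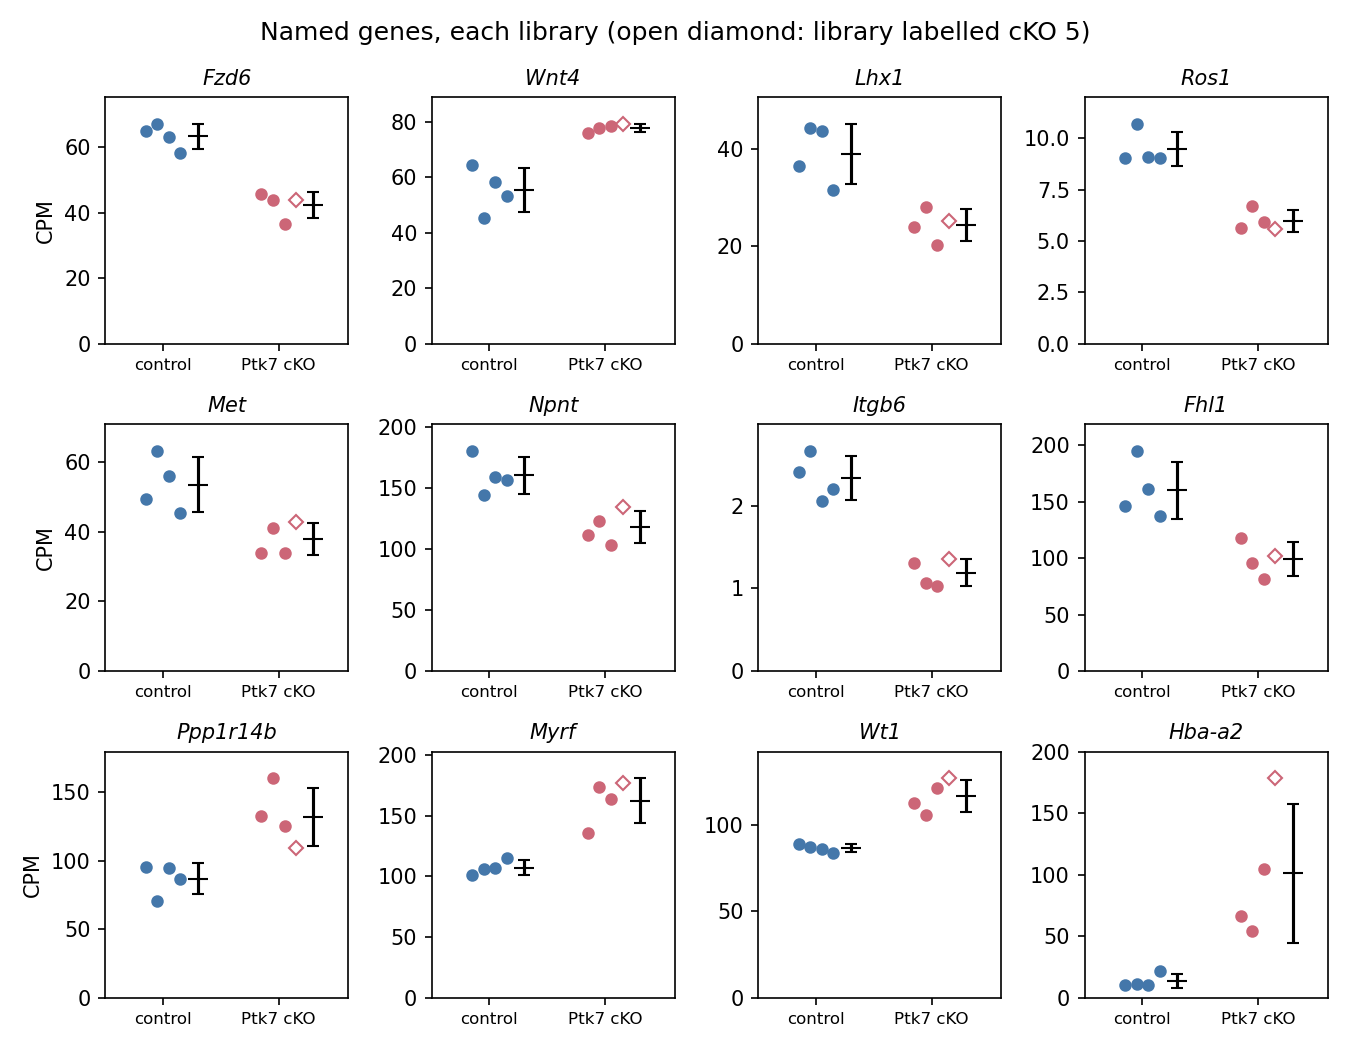
CPM (vertical axis, from 0) of 12 of the 63 named genes, picked for plotting after their values were seen, with 1 point per library, blue for control and red for the knockout label, and the mean with its SD (n = 4) in black beside each group. The open diamond is the library labelled Ptk7 cKO 5; Fzd6 lies between 58.1 and 67.0 CPM in control and between 36.6 and 45.6 in the knockout label.

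Smooth muscle differentiation genes fell as a set (33 genes, median log2 fold change -0.17, 21 below 0, camera adjusted p = 1.74e-05). The call was lost when the correlation between genes was estimated (adjusted p = 0.399 with an estimated correlation). Of these genes 5 fell when adjusted over the list alone. Among them were Fhl1 (160 ± 25.4 CPM against 99.1 ± 14.9, log2 fold change -0.69, SE 0.13, edgeR adjusted p = 0.00484 over the list alone), Casq2 (-0.66, 0.0315), Ldb3 (-1.04, 0.0392) and Acta2, the smooth muscle actin (-0.36, 0.0392). Des, the muscle intermediate filament gene, had 167 CPM in control and 206 in knockout, without passing over the list alone (edgeR adjusted p = 0.0697). Of the 33 genes 6 are also in another list. The mean score of the list was 0.095 ± 0.12 in control and -0.095 ± 0.071 in the knockout label (SD, n = 4 each). The exact two-sided permutation p was 0.0286, the smallest possible. The groups did not overlap, by a narrow margin: control 3 stood at -0.0465 and the library labelled Ptk7 cKO 5 at -0.0482.

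Duct epithelium markers fell as a set (36 genes, median log2 fold change -0.27, 31 below 0, camera adjusted p = 1.12e-09; adjusted p = 0.399 with an estimated correlation). Of these, 5 fell when adjusted over the list alone. Among them were Esrp1, an epithelial splicing regulator (39.5 ± 6.53 CPM against 26.7 ± 3.70, log2 fold change -0.56, SE 0.13, edgeR adjusted p = 0.0310 over the list alone), Grhl2 (-0.57, 0.0387) and Cdh1, or E-cadherin (-0.52, 0.0387). The most abundant members did not: Epcam had a log2 fold change of -0.18 (edgeR adjusted p = 0.20 over the list alone) and Krt8 of 0.12 (0.593). The mean score of the list was 0.11 ± 0.10 in control and -0.11 ± 0.14 in the knockout label (SD, n = 4 each, exact two-sided permutation p = 0.0857). The groups overlapped: the library labelled Ptk7 cKO 2 stood at 0.080, above controls 3 (0.070) and 6 (-0.016).

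Mesothelium markers rose as a set (14 genes, median log2 fold change 0.34, 12 above 0, camera adjusted p = 1.10e-08; adjusted p = 0.399 with an estimated correlation), and 5 rose when adjusted over the list alone. These included Myrf (107 ± 5.91 CPM against 163 ± 18.6, log2 fold change 0.60, SE 0.09, edgeR adjusted p = 0.000699 over the list alone) and Wt1 (86.4 ± 2.24 against 117 ± 9.39, 0.43, SE 0.07), a transcription factor also found in the testis list. Of the 14 genes 4 are also in another list, and Msln, the mesothelin gene, had a log2 fold change of -0.12. The mean mesothelium score was -0.15 ± 0.19 in control and 0.15 ± 0.24 in the knockout label (SD, n = 4 each, exact two-sided permutation p = 0.143), and the groups overlapped: control 6 stood at 0.083, above the libraries labelled Ptk7 cKO 1 (-0.015) and 4 (-0.087). Neuron and Schwann cell markers rose as a set (18 genes, median log2 fold change 0.64, 15 above 0, camera adjusted p = 1.50e-06; adjusted p = 0.399 with an estimated correlation), and 5 passed over the list alone. Among them were Stmn2, a neuronal microtubule regulator (32.6 ± 4.54 CPM against 50.6 ± 16.9, log2 fold change 0.64, SE 0.20, edgeR adjusted p = 0.0414 over the list alone), and Hand2 (0.66, SE 0.17, same adjusted p). The mean neuron and Schwann cell score was -0.24 ± 0.13 in control and 0.24 ± 0.24 in the knockout label (SD, n = 4 each). Its groups did not overlap (exact two-sided permutation p = 0.0286, the smallest possible). For Stmn2 the groups overlapped: the library labelled Ptk7 cKO 5 had 37.7 CPM and control 4 had 38.5. Erbb3, next to Stmn2 in level in this list, went the other way without passing (29.0 ± 3.63 CPM against 25.5 ± 3.76, log2 fold change -0.19, SE 0.12, edgeR adjusted p = 0.242 over the list alone). The calls of smooth muscle, duct epithelium, mesothelium and neuron lists were kept without the library labelled Ptk7 cKO 5 (camera adjusted p = 6.84e-06, 7.26e-08, 5.20e-05 and 7.26e-08). Adjusted over all lists, none of the 4 score differences passed (permutation adjusted p = 0.40, 0.48, 0.571 and 0.40).

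Mesenchyme markers rose by a small median (26 genes, median log2 fold change 0.10, camera adjusted p = 0.0294; adjusted p = 0.577 with an estimated correlation). Prrx2 passed over the list alone (log2 fold change 0.63, SE 0.13, edgeR adjusted p = 0.0173). The 45 cell cycle genes fell (median -0.06, camera adjusted p = 0.0418; adjusted p = 0.807 with an estimated correlation). The mesenchyme call was lost without control 4 (0.0856), without the library labelled Ptk7 cKO 4 (0.131) or without the library labelled Ptk7 cKO 5 (0.0536). The cell cycle call was lost without control 3 (0.708), control 4 (0.0856), or the library labelled Ptk7 cKO 1 (0.146) or 4 (0.0620). Erythroid genes rose as a set (12 genes, median 0.36, camera adjusted p = 0.00511; adjusted p = 0.777 with an estimated correlation) and mitochondrially encoded genes fell (15 genes, median -0.21, camera adjusted p = 0.00933; adjusted p = 0.807 with an estimated correlation). Both calls were lost without the library labelled Ptk7 cKO 5 (0.202 and 0.626). The mitochondrial share of its counts was 1.82%, against 2.37% to 3.47% elsewhere. The mitochondrial call was also lost without control 3 (0.248). None of these 4 lists passed fry's mixed test (adjusted p = 0.0523 for mesenchyme, 0.0611 for erythroid and 0.377 each for cell cycle and mitochondrial genes). The alpha globin Hba-a2 rose over the list alone (13.5 ± 5.72 CPM against 101 ± 56.2, log2 fold change 2.90, SE 0.39, edgeR adjusted p = 0.000182 over the list alone). Its near-identical copy Hba-a1 had a log2 fold change of 0.28 (SE 0.42), so the division of reads between them is uncertain.

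**Figure D3:**
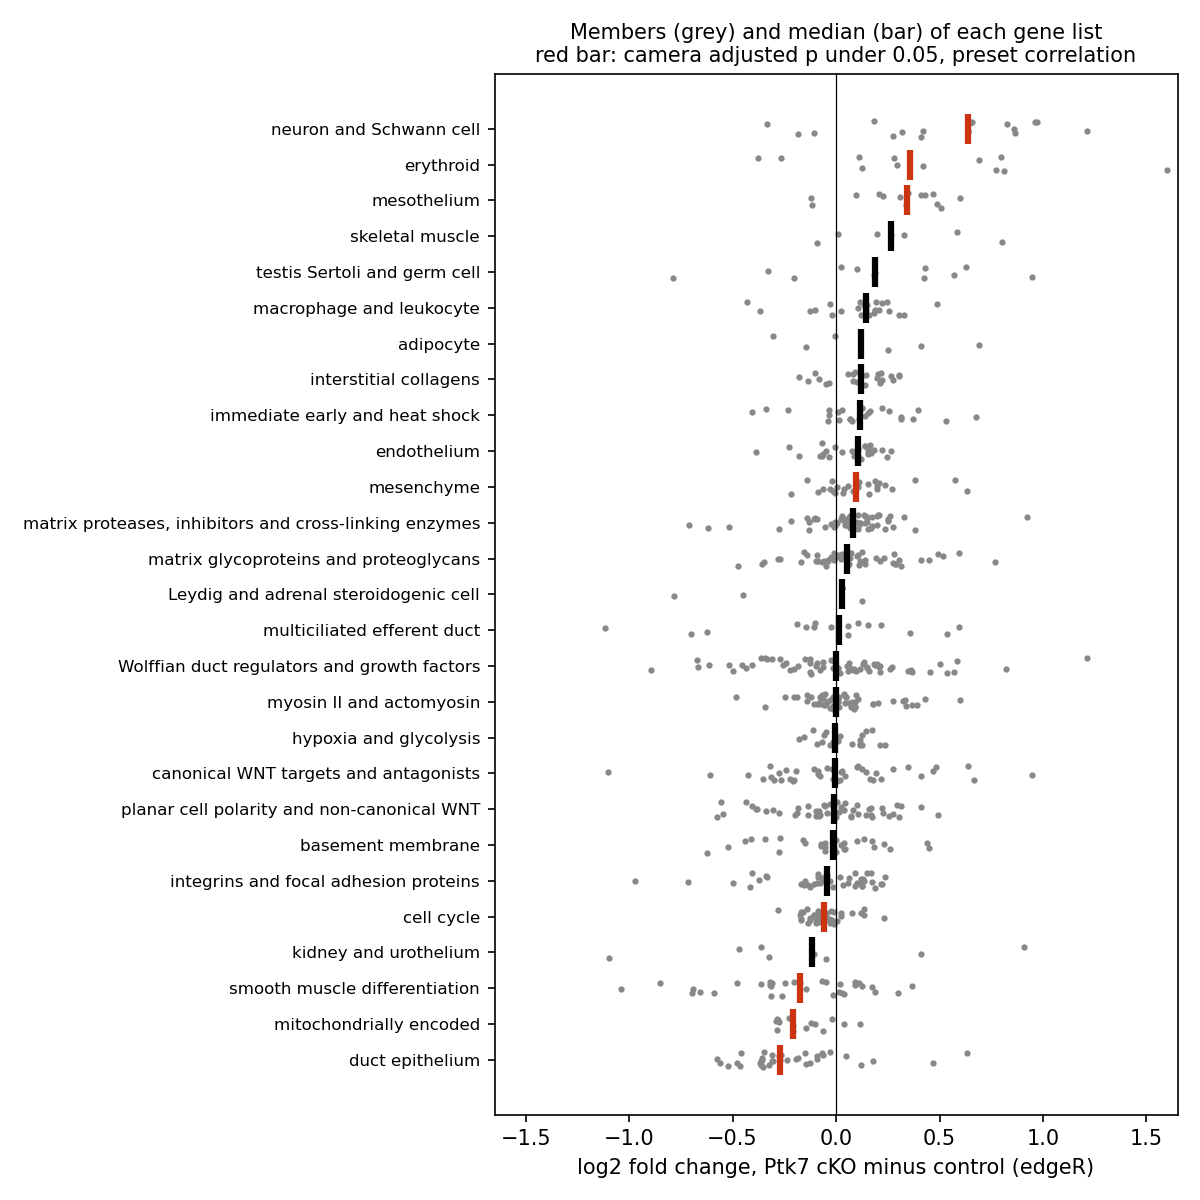
Log2 fold change of each tested member (grey points, horizontal axis, knockout label minus control) and the median (bar) of 27 gene lists, ordered by median, red where the camera adjusted p with a preset correlation was under 0.05. The median ranges from -0.27 for duct epithelium to 0.64 for neuron and Schwann cell markers, and 1 member beyond 1.6 is drawn at that limit.

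The other lists of cell types and states were not called: endothelium (camera adjusted p = 0.345), macrophage and leukocyte (0.0685), testis (0.0598), Leydig and adrenal cells (0.356), multiciliated efferent duct cells (0.921), kidney and urothelium (0.869), skeletal muscle (0.0685), adipocyte (0.345), immediate early and heat shock genes (0.120), and hypoxia and glycolysis (0.626). Macrophage and leukocyte markers were called higher with no filter on low counts (0.0329), and testis markers with no filter (0.0432) or at a minimum CPM of 1 (0.00809). With an estimated correlation over all 8 libraries the adjusted p was 0.895 for endothelium, 0.399 for testis and 0.807 each for macrophage and leukocyte, skeletal muscle, and immediate early and heat shock genes. In fry's mixed test testis (0.00321), multiciliated (0.0263) and kidney and urothelium (0.0361) lists passed, and the others of these lists did not (0.143 to 0.759). Hypoxia and glycolysis was called lower under the replicate block over 4 libraries (0.0186), the opposite direction from the 8 libraries. At the preset correlation some lists were called higher when 1 library was left out. This held for endothelium without the library labelled Ptk7 cKO 2 (0.00157), for skeletal muscle without control 6 (0.0157), and for immediate early and heat shock genes without control 4 (0.00579) or the library labelled Ptk7 cKO 4 (0.0176). It held for macrophage and leukocyte markers without control 1 (0.0309), 4 (0.0454) or 6 (0.0138) or the library labelled Ptk7 cKO 2 (0.000739). It also held for testis markers without control 1 (0.0325) or 4 (0.04998) or the library labelled Ptk7 cKO 1 (0.0417) or 5 (0.0392). In the multiciliated list Tppp3 rose over the list alone (log2 fold change 0.53, SE 0.12, edgeR adjusted p = 0.0125), as did Upk1b in the kidney and urothelium list (0.41, SE 0.09, 0.00708), Lpl in the adipocyte list (0.25, SE 0.07, 0.0412) and Wt1 in the testis list (0.0012). Control 3 lay apart from the other libraries on the first principal component (48.2, against -27.6 to 6.64 elsewhere), which held 28.1% of the variance.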

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

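All tests of explanations in this part were chosen after the results were seen. Of 184 groups of 4 libraries, 16 held a library far from the others of its group, where chance gives 9.2. The library labelled Ptk7 cKO 5 held 5 of these and control 3 held 5.

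Ptk7 in the library labelled Ptk7 cKO 5 stood at 194.3 CPM, against 7.33 to 12.5 in the other 3 libraries of that label. An exchange with a control library of the series is argued against, because the lowest control had 8.99 times the Ptk7 CPM of the highest of those 3, so no control lacks Ptk7. A single control library under a wrong label stays open. Placed between the control mean (0) and the knockout mean (1) over 200 genes outside chromosome 17, with each library left out in turn, it lay at 0.498, where controls ranged from -0.020 to 0.602 and the other knockouts from 0.264 to 0.769. That the disrupted chromosome is present and only the floxed allele stayed intact also stays open. Over 20 genes within 15 Mb of Ptk7 it lay at 0.035, where controls ranged from -0.213 to 0.861 (the highest being control 3) and the other knockouts from 0.306 to 1.09. Sets of 10 and 40 such genes gave -0.046 and 0.018. It thus lay below the other knockouts, and it also lay apart from them in H2-T10 (4.70 CPM, other knockouts 0.19 to 0.61) and Rps18 (243, other knockouts 501 to 585). This cannot decide the question, because control 3 lay among the knockouts in the same measure and in H2-T10 (0.47 CPM). Control 3 was also nearer to them than to the other controls in Rps18 (412, other controls 229 to 284). These values thus do not mark the disrupted chromosome. In genes nearer to Ptk7, control 3 lay with the controls, and the library labelled Ptk7 cKO 5 left the other knockouts toward them. These were Polh (29.61 CPM, other knockouts 19.19 to 21.38, control 3 at 27.83), Xpo5 (60.1, 50.6 to 55.9, 72.9), Dnph1 (27.9, 32.2 to 34.5, 23.6) and Nfkbie (8.916, 4.199 to 4.998, 6.392). Picked after their values were seen, they go against that chromosome being present but do not decide the question. H2-DMb2, also near Ptk7, was on the side of the label (4.17 CPM, other knockouts 2.67 to 3.43, controls 6.16 to 8.02). So was Hba-a2 on chromosome 11 (178.9 CPM, controls 10.1 to 22.1), in a library that stood apart in other globin genes too. The globin level alone does not account for this. Control 6 had 22.1 CPM of Hba-a2 beside 879 of Hba-a1, and the other knockouts had 54.1 to 105 beside 334 to 492. Hba-a2 is a single gene whose reads are hard to divide from Hba-a1, so it does not decide the question. Amhr2 on chromosome 15 lay with the controls (2.29 CPM, controls 1.96 to 2.90, other knockouts 5.91 to 7.17). The overlap of the ranges outside chromosome 17 keeps the wrong label open, and loss of recombination in this embryo, which may leave Ptk7 at a control level, was not tested otherwise.

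Duct epithelium markers were lower and mesothelium markers higher in the libraries labelled knockout, a label that the library labelled Ptk7 cKO 5 contradicts by its Ptk7. That control 3 alone makes the duct epithelium part is argued against, since its score lay below the mean of the other controls (difference -0.050). For the mesothelium part this stays open: without control 3 the score difference was 0.23, or 1.49 times its SE of 0.15, against 0.29 with all 8 libraries. A lower share of duct epithelium alone would raise the markers of every other cell type alike, and this stays open. Of the 13 lists of other cell types 9 had a higher score and 4 a lower one. The SD of their score differences was 0.241, and 1 of the 35 splits of the libraries, the real one, gave an SD as large (median 0.161). This also held with mesothelium and erythroid lists left out, but 3 of the 35 splits gave an SD as large when the neuron and Schwann cell list was left out. An earlier comparison of mesothelium with smooth muscle, lists picked for moving apart, was dropped, as was one of the duct epithelium score without control 3. More mesothelium in the dissected tissue and an effect of Ptk7 loss on the duct stay open and untested.

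The library labelled Ptk7 cKO 5 also stood apart in Ppp1r12b (73.0 CPM, others 66.7 to 67.8), Hbb-bs (2110, others 758 to 841), Hba-a1 (1290, others 334 to 492) and the erythroid score (1.01, others -0.047 to 0.0096). Control 3 stood apart in Ros1 (10.7 CPM, others 9.05 to 9.08), Ccnb1 (83.2, others 64.9 to 66.9), Hand2 (10.3, others 18.4 to 18.97), mt-Cytb (6641, others 4523 to 4860) and the macrophage and leukocyte score (-0.43, others 0.058 to 0.12). Control 1 stood apart in Myl9 (687 CPM, others 573 to 588), and control 6 in Hba-a2 (22.1 CPM, others 10.1 to 11.2). The library labelled Ptk7 cKO 2 stood apart in Thbs4 (17.5 CPM, others 9.96 to 11.1), Epcam (298, others 215 to 221) and the multiciliated score (-0.27, others 0.024 to 0.055), and the library labelled Ptk7 cKO 4 in the smooth muscle score (-0.20, others -0.071 to -0.048).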

How the results depend on the processing

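Fits without the library labelled Ptk7 cKO 5 by DESeq2 or voom, without it and control 3, and with robust moderation were added after seeing the data. With all 8 libraries edgeR called 0 genes (1379 at an unadjusted p under 0.05), as it did with DESeq2 size factors, upper-quartile factors, a minimum CPM of 1, robust moderation and 1 surrogate variable, and as voom did. DESeq2 called 186 genes, 58 higher and 128 lower. Without the library labelled Ptk7 cKO 5, DESeq2 called 188, 69 higher and 119 lower, and voom 7, 4 higher and 3 lower. With no filter on low counts edgeR called 1 gene, 1 higher (Hba-a2). Without that library and control 3 it called 3, with 1 higher (Rps18) and 2 lower (H2-T10 and Ptk7). Leaving out each library in turn gave 0 to 2 genes, 0 to 2 higher and 0 to 1 lower: Gm9826 and Ahcy without control 1, and Ptk7 without the library labelled Ptk7 cKO 5. Genes at an unadjusted p under 0.05 ranged from 955 (surrogate variable) to 2133 (voom without the library labelled Ptk7 cKO 5). No setting moved the median log2 fold change of all genes by over 0.1. The genes named here outside the rule were chosen after their values were seen. Why DESeq2 and edgeR differ was not tested.

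The numbers in the titles are shared by 2 libraries of each group, 1 and 4. What they mark is not stated, and the libraries did not deviate together (correlation -0.092 for number 1 and 0.023 for number 4), so they were not treated as paired. A replicate block over these 4 libraries gave 7 genes, 5 higher and 2 lower, against 4 for the same libraries without the block, and a Ptk7 log2 fold change of -4.67. Under the block the camera adjusted p at the preset correlation was 0.000836 for interstitial collagens, 0.0481 for myosin II and 0.0186 for hypoxia and glycolysis, each in the opposite direction from the 8 libraries, and 0.385 for mitochondrial genes, also in the opposite direction. It was 4.72e-07 for basement membrane, 0.00088 for integrins, 0.00814 for planar cell polarity and 0.0344 for Wolffian duct regulators, now called, and 0.219 for cell cycle, no longer called. Over all 8 libraries with an estimated correlation the p was 0.895 for basement membrane, 0.823 for integrins and Wolffian duct regulators and 0.807 for planar cell polarity. The block rests on 4 libraries only, and the cause was not tested.

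The log2 fold change of Ptk7 was -4.42 by DESeq2 and -4.68 by voom without the library labelled Ptk7 cKO 5, and -4.61 by edgeR without it and control 3. Leaving out each library in turn it ranged from -4.42 to -1.46. Of 1220 values of named genes under the alternatives, 13, all uncalled, changed sign. Of 486 list values 44, uncalled in both fits, changed direction, as did 6 with a call in either fit, each given here.

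The duct epithelium, mesothelium, neuron and smooth muscle calls were kept under every alternative run for lists (not DESeq2's test, voom without the library labelled Ptk7 cKO 5 or robust moderation) except the estimated correlation (adjusted p = 0.399 for each) and fry (0.228 for each). Both also ended the calls of mesenchyme (0.577 and 0.228), erythroid (0.777 and 0.654), cell cycle and mitochondrial genes (0.807 and 0.712 for each). Under voom the p was 0.113 for mesenchyme, 0.181 for erythroid and 0.203 for cell cycle and for mitochondrial genes. With the surrogate variable it was 0.0613 for mesenchyme, 0.175 for erythroid, 0.706 for mitochondrial genes and 0.488, in the opposite direction, for cell cycle. Without the library labelled Ptk7 cKO 5 and control 3 it was 0.323 for cell cycle, 0.565 for erythroid, 0.573 for mitochondrial genes, in the opposite direction, 0.00556 for basement membrane and 0.0103 for integrins. With no filter it was 0.0329 each for collagens, matrix glycoproteins, matrix proteases and macrophage and leukocyte markers and 0.0432 for testis markers, which had 0.00809 at a minimum CPM of 1. Leaving out each library in turn, the p ranged from 0.00195 to 0.887 for collagens, 0.0266 to 0.837 for basement membrane, 0.00482 to 0.653 for glycoproteins, 0.00268 to 0.688 for proteases, and 0.0201 to 0.913 for integrins. It ranged from 0.00266 to 0.708 for cell cycle, 0.00439 to 0.131 for mesenchyme, 8.62e-05 to 0.202 for erythroid and 3.18e-05 to 0.626 for mitochondrial genes. The cause was not tested for any of these.

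Over the 35 splits of the 8 libraries into 4 and 4, 2 gave as many genes at an unadjusted p under 0.05 in edgeR (real 1379, highest other 1679), so chance cannot be excluded for that count. The higher one exchanges control 6 and the library labelled Ptk7 cKO 5. All 35 gave as many edgeR calls as the real 0 (highest other 3). For DESeq2 1 of the 35 splits, the real one, gave 186 (highest other 97), which argues against chance for that count but does not exclude it. It is the smallest share that 35 splits can give, and the edgeR counts did not argue against chance. Depth limits only low genes: at 24807970 or more counts per library, the spread between libraries sets the precision of the rest.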

Other observations

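The genes named here, Fisher's exact test and the fit without the library labelled Ptk7 cKO 5 were chosen after the results were seen; the DESeq2 test on all 8 libraries was fixed beforehand. Among the 118 genes that DESeq2 called with all 8 libraries and without the library labelled Ptk7 cKO 5, 41 were higher and 77 lower. The lower ones included Scnn1a, a subunit of the epithelial sodium channel (log2 fold change -1.05, adjusted p = 0.000108), the gap junction gene Gja1 (-0.61, 0.00566), and the desmosome gene Dsp (-0.45, 0.0137). Also lower were 3 GABA receptor subunit genes on chromosome 5, Gabrg1 (-1.13, 0.00106), Gabrb1 (-0.75, 0.00885) and Gabra4 (-0.52, 0.00777). Another subunit gene, Gabra3, was called higher with all 8 libraries (0.63, 0.0196), and the subunits were not tested as a set. Higher genes included Alx1 (0.75, 0.000158), Igfbp5 (0.43, 0.00299), Cebpb (0.87, 0.000335) and Id3 (0.41, 0.00372). edgeR called none of these. In simulated counts the false calls of DESeq2 exceeded its nominal share, so some of these calls may be false.

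Amhr2, the receptor of anti-Müllerian hormone, was higher by DESeq2 (log2 fold change 1.16, adjusted p = 0.0249; edgeR adjusted p = 0.298). Its level was 5.91, 7.17 and 7.02 CPM in the libraries labelled Ptk7 cKO 1, 2 and 4, and 2.29 CPM in the library labelled Ptk7 cKO 5, where controls ranged from 1.96 to 2.90. The pattern was seen in the same data and was not tested apart from them.

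H2-T10, H2-DMb2 and Rps18, which lie on chromosome 17 within 15 Mb of Ptk7, differed between the libraries. H2-T10 stood at 0.61, 0.19 and 0.23 CPM in the libraries labelled Ptk7 cKO 1, 2 and 4 and at 0.47 in control 3, against 4.70 in the library labelled Ptk7 cKO 5 and 4.82 to 4.96 in controls 1, 4 and 6. Rps18 stood at 585, 536 and 501 CPM in the libraries labelled Ptk7 cKO 1, 2 and 4 and at 412 in control 3, against 243 in the library labelled Ptk7 cKO 5 and 229 to 284 in controls 1, 4 and 6. H2-DMb2 did not share this pattern and followed the labels: it stood at 3.03, 3.43, 2.67 and 4.17 CPM in the libraries labelled Ptk7 cKO 1, 2, 4 and 5, at 6.16 in control 3 and at 7.34 to 8.02 in the other controls. A candidate explanation is a strain haplotype carried with the disrupted chromosome. Genes within 15 Mb of Ptk7 passed an unadjusted p under 0.05 in 9.97% of 331 cases, against 8.71% elsewhere, without the library labelled Ptk7 cKO 5 (odds ratio 1.16, interval 0.781 to 1.67, Fisher's exact p = 0.431), which leaves the explanation open. The odds ratio without that library was 1.63 within 5 Mb and 0.896 within 30 Mb, and 0.981 within 15 Mb with all 8 libraries, each with an interval that included 1. Each of these fits kept control 3 among the controls, although it lay with or near the knockouts in H2-T10 and Rps18. For that reason too the odds ratio cannot decide the question. The bound that counts against it was changed after this value was seen: at first an interval that included 1 counted against it, and by that bound the value would argue against a haplotype; it was replaced because an interval reaching 1.67 does not exclude an excess.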
